A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

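Photoactivatable-ribonucleoside-enhanced crosslinking and immunoprecipitation (PAR-CLIP) recovers RNA crosslinked by UV light to a tagged protein. Here it was applied to budding yeast, Saccharomyces cerevisiae, and the molecule is given as nuclear RNA per the labels. The series holds 10 samples in 5 groups of 2. Of these, 6 libraries in 3 groups have values that were used: the cassette control without rapamycin, a Nab3-FRB strain with rapamycin, and an Nrd1-FRB strain with rapamycin for 45 min. The other 4 samples, Nab3-FRB without rapamycin and a Nab-HTB strain without rapamycin, were not analysed here because no value column in the tables used belongs to them. The study's design text names RNA polymerase II (Pol II) as the protein mapped. Only the Nrd1-FRB samples name the tagged Pol II subunit, Rpb2-HTB. What the cassette is was not given in the sources used here, and neither was the rapamycin time of the Nab3-FRB libraries. An FRB tag lets rapamycin tether a protein to an anchor outside the nucleus, so that the protein is removed from the nucleus while its gene stays intact.

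The deposited per-library values are a normalised signal: read counts per gene that the authors divided by 1 size factor per library, separately in each of 2 tables. The values themselves show this, since 100% of them in every column are whole multiples of the value of 1 read within 0.01 reads. Bowtie 1.1.1, DESeq and the genome builds R64 and sacCer3 are named per the submitters' processing notes, with no order or settings. The read counter, its strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited comparison tables hold log2 fold changes of group means, p-values and adjusted p-values, per the file headers. Their gene length column, also deposited by the authors, was used only to match features on length.

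Each table holds 6677 features, all of them protein-coding or putative open reading frames by name. Of these, 5915 were matched to the RefSeq annotation of assembly R64 by symbol, locus tag or synonym and 762 were not. For 5909 of the matched features the deposited length equals the annotated length minus 1, so coordinates are given on R64. Unmatched features are mostly systematic names with no entry there, and no position is given for them. No snoRNA, snRNA, tRNA, cryptic transcript or retrotransposon feature was found by name, so those 5 lists were not tested.

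Recovered reads gave the depth: 12084304 and 9584474 reads for the cassette libraries, 13428820 and 9046857 for the Nab3-FRB libraries, and 7395659 and 8077260 for the Nrd1-FRB libraries. At these depths, simulated data with the real means and library sizes recovered 61 of 67 genes changed 1.5-fold in the Nab3 comparison (6314 genes tested) and 62 of 67 in the Nrd1 comparison (6262 genes tested) with limma. In the same simulations 12 of 6114 and 19 of 6062 unchanged genes were called. For the comparison between depletions, 63 of 67 genes changed 1.5-fold were recovered among 6279 tested. In the simulated Nab3 comparison, the only one in which lists were tested, camera called the 1 raised list and 0 of 19 unchanged lists. Simulated genes varied independently of each other, so this does not give the false calls expected for lists of correlated genes. The spread of each gene was the same in all groups, so the gene counts do not cover groups of unequal spread.

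Columns were assigned to samples by name. The Nab3-FRB columns carry the numbers 2 and 3 while the sample titles carry 1 and 2, so these columns were assigned to the group only and are called Nab3 libraries 2 and 3. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Within groups, the chi-square statistic of the recovered reads per degree of freedom was 3.03 for the cassette, 5.03 for the Nab3 and 11.4 for the Nrd1 libraries, above counting noise, as repeats of 1 preparation could also be. The libraries were counted as replicates because the labels number them so.

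Tests were fitted on log2(value + 1) for features with a mean of at least 10, with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, R 4.3.3), Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low features. Every adjusted p without another tool named comes from limma. The 2 tables were fitted separately. The cassette columns of both tables were proportional (Pearson r = 0.99995 for both libraries across features, which are not independent replicates), so the Nrd1-FRB values were multiplied by 1.18 and the 6 libraries were fitted together for the difference between depletions. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 5 members tested, with adjustment over lists. The same test with an estimated correlation was run beside it. That setting also tests each list on the residual degrees of freedom, 2 per depletion and 3 for the difference. It can therefore lose calls without any correlation between genes, and a lost call does not show that correlation undoes it.

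Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for named genes were fixed, except for the final members of the list of genes downstream of snoRNA. That rule takes, per depletion, the 10 largest rises and the 10 largest falls among features past the threshold whose depleted values lie on the same side of both cassette values and whose mean reaches 50 in a group. It adds the 2 highest and 2 lowest members of each list, NAB3, NRD1, SEN1, RPB2, TOR1 and FPR1, and the 5 largest differences each way between depletions. The list of genes downstream of snoRNA holds protein genes that start within 1 kb 3′ of an annotated snoRNA on the same strand. Its members were first fixed as TRS31, YCR015C, YDR042C and LIN1 and were then replaced by this annotation criterion. LIN1, with a log2 fold change of -1.96 after Nab3 depletion, is not in the list that was tested. The alternatives tried were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, upper-quartile scaling, scaling to the protein-coding total, eBayes without trend, a replicate block, leaving out each library, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. A restriction to features with a reference entry and the authors' own gene marks as lists were added after seeing the data. The overlap and the authors' calls were also counted at an adjusted p under 0.01. Unchanged groups were simulated 50 times from the cassette means to show what correlation and covariance of log2 fold changes noise between libraries gives when controls are shared.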

Results

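Nuclear RNA crosslinked to a tagged protein was measured in yeast after nuclear depletion of Nab3 or Nrd1, the RNA-binding subunits of the Nrd1-Nab3-Sen1 complex, which ends transcription of many short noncoding RNAs and of some mRNA genes near their start. The cassette strain without rapamycin served as control for both. The tagged protein is taken to be Pol II in all groups from the study's design text, since the labels name a Pol II subunit only for the Nrd1-FRB libraries. Each group had 2 libraries, with 7395659 to 13428820 recovered reads per library. Values are reads per gene divided by the authors' size factor, given as mean ± SD with n = 2. Intervals given for ratios of reads cover counting error only, because reads without molecular identifiers are not independent molecules. Strain, depletion and rapamycin changed together in both comparisons, so a difference belongs to that combination, and to the tagged protein too if that differed between groups.

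The genes of the depleted proteins and of their partners were read in every library. NAB3 had 2542 and 2573 normalised reads in the cassette libraries, 2277 and 2312 after Nab3 depletion, and 2290 and 2403 after Nrd1 depletion on the joint scale. Its log2 fold change was -0.16 after Nab3 depletion (adjusted p = 0.027), a call lost without cassette library 1 (adjusted p = 0.152) or 2 (adjusted p = 0.193, the highest of the settings tried), without the trend in eBayes and with DESeq2, and -0.12 after Nrd1 depletion (adjusted p = 0.126). NRD1 (chromosome XIV, 172588 to 174315, minus strand) had 1959 and 2103 in the cassette libraries, against 7487 and 8536 after Nab3 depletion and 8806 and 8252 after Nrd1 depletion. SEN1, the helicase of the complex (chromosome XII, 993434 to 1000129, plus strand), had 1490 and 1542 in the cassette, 3081 and 2956 after Nab3 depletion, and 3474 and 3169 after Nrd1 depletion. RPB2, which encodes a Pol II subunit, lay between 5456 and 5848 in all 6 libraries. TOR1, the rapamycin target kinase, lay at 3749 and 3810 in the cassette and between 4125 and 4562 in the depleted libraries (log2 fold change 0.21 after Nab3 depletion, adjusted p = 0.00446, or 0.0582 without cassette library 1, and 0.20 after Nrd1 depletion, adjusted p = 0.0605). FPR1, the rapamycin-binding protein, had 77 to 184 recovered reads per library and log2 fold changes of -0.64 and -0.54. The call after Nrd1 depletion (adjusted p = 0.0402) was lost without cassette library 1 (adjusted p = 0.313, the highest of the settings tried) or 2 (adjusted p = 0.224) and with DESeq2. Because the anchor removes protein from the nucleus and leaves the gene intact, these reads do not check the depletion.

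**Figure D1:**
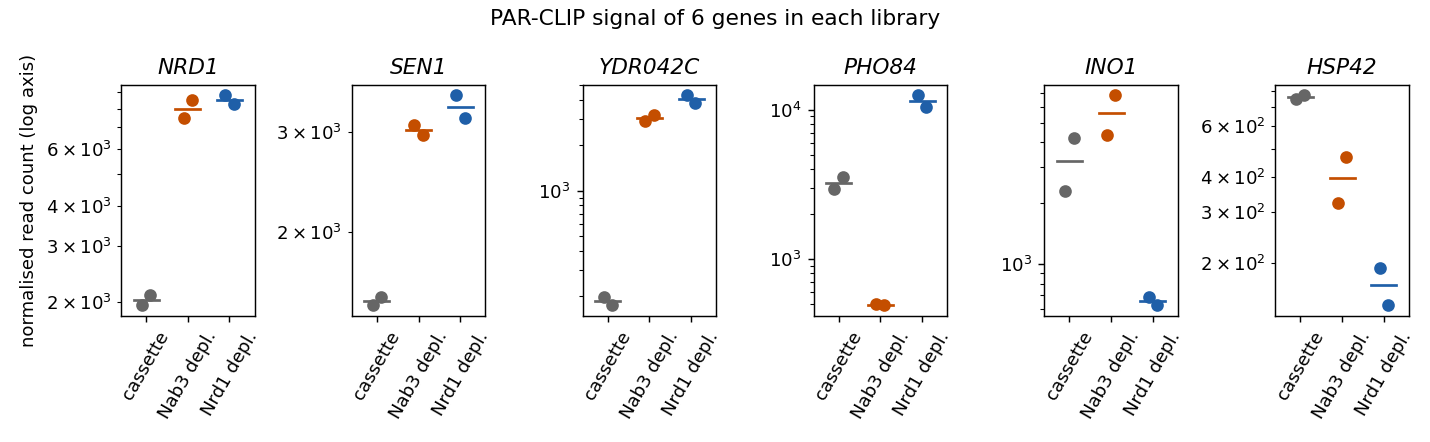
Normalised PAR-CLIP reads (log axis, joint scale) of 6 genes in each library; points are the 2 libraries of a group and bars their mean. NRD1, SEN1 and YDR042C lie higher in both depleted groups than in the cassette, PHO84 lies at 493 after Nab3 depletion against 11405 after Nrd1 depletion, and INO1 lies at 5568 against 655.

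The comparison of Nab3 depletion with the cassette asked on which genes the signal, taken as that of Pol II, changes when Nab3 leaves the nucleus. Signal rose on 27 of 36 nitrogen-utilisation genes, 15 of 23 amino acid permeases, 7 of 9 genes with known early termination and 15 of 32 genes behind snoRNAs, and fell on 18 of 21 chaperone and 9 of 16 phosphate-starvation genes. The list calls were lost with an estimated correlation (adjusted p = 0.226 to 0.408 for these lists with an estimated correlation). That setting tests on 2 residual degrees of freedom, so the loss does not show that correlated genes made the calls. NRD1 rose 3.94-fold, from 2031 ± 102 to 8011 ± 742 normalised reads (log2 fold change 1.98 ± 0.06 SE, adjusted p = 1.75e-11). The nitrogen gene DAL80, a GATA-type repressor, rose 4.59-fold, from 124 ± 20.7 to 570 ± 8.56 (2.20 ± 0.12 SE, adjusted p = 5.65e-09). PHO84, the high-affinity phosphate transporter, fell 6.50-fold, from 3221 ± 415 to 493 ± 4.69 (-2.70 ± 0.08 SE, adjusted p = 4.53e-12). An annotated noncoding RNA overlaps PHO84, and the strand setting of the counts is not given. Of 6360 features tested, 1341 rose and 1187 fell, of which 215 rose and 54 fell at least 2-fold. Scaling turned that balance: upper-quartile scaling gave 1191 rises and 1488 falls, and scaling to the protein-coding total gave 1180 and 1428.

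Among the 36 tested members of the nitrogen catabolite repression list, genes held down while good nitrogen sources last, 27 rose and 1 fell, and 8 did not pass (27 and 1 adjusted over the list alone). The list median was 0.48 in log2 (camera adjusted p = 1.62e-08, and adjusted p = 0.226 with an estimated correlation). The largest rises in it were DAL80 and UGA4, a GABA permease, at 1.84 (chromosome IV, 84270 to 85985). UGA1, which encodes GABA transaminase, fell with a log2 fold change of -0.27. The ASP3-1 to ASP3-4 copies had a mean under 10 and were not tested. Of 23 amino acid permeases 15 rose and 1 fell (16 and 2 adjusted over the list alone), led by UGA4 and AGP3 at 1.73, with a list median of 0.40 (adjusted p = 7.53e-06, and adjusted p = 0.226 with an estimated correlation). The permease and nitrogen lists share AGP1, GAP1, PUT4 and UGA4.

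Of 9 tested mRNA genes known for early termination by the complex 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.65 (adjusted p = 0.000912, and adjusted p = 0.375 with an estimated correlation). IMD2, an IMP dehydrogenase of guanine nucleotide synthesis (chromosome VIII, 554396 to 555967), rose 6.41-fold, from 836 ± 22.5 to 5363 ± 256. Reads of IMD2 may be shared with its near-identical copies, so its value is uncertain. TIS11 fell at -0.35, a call lost without the trend in eBayes. The nucleotide biosynthesis list shares IMD2, URA2, URA8 and ADE12 with that list, so the calls are not separate results. It had 9 rises and 1 fall among 14 members (9 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.00204, and adjusted p = 0.253 with an estimated correlation). URA8, a CTP synthase, rose 3.82-fold in it, and URA5 fell at -0.44. Of 32 genes downstream of a snoRNA 15 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.00469, and adjusted p = 0.253 with an estimated correlation). YDR042C, an open reading frame of unknown function on chromosome IV (540601 to 541203, minus strand), rose 16.2-fold, from 187 ± 16.9 to 3040.4 ± 179. RGT1, a regulator of glucose transporter genes, rose 2.68-fold. LIN1, named in the first version of this list but not in the tested one, fell at -1.96.

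Methionine and sulfur genes had 15 rises and 1 fall among 25 members (15 and 1 adjusted over the list alone, median 0.34, adjusted p = 2.17e-05, and adjusted p = 0.226 with an estimated correlation). SAM2, an S-adenosylmethionine synthetase that has a close paralog, rose 2.97-fold, the sulfate permease gene SUL2 rose 2.37-fold, and JLP1 fell at -0.62. Among 48 Gcn4-driven biosynthetic genes 25 rose and 5 fell (27 and 5 adjusted over the list alone, median 0.18, adjusted p = 0.000602, and adjusted p = 0.396 with an estimated correlation). MET6, which encodes methionine synthase, rose at 1.21. Ergosterol genes had 16 rises and 0 falls among 24 members (17 and 0 adjusted over the list alone, median 0.24, adjusted p = 7.63e-05, and adjusted p = 0.226 with an estimated correlation), with HMG1 at 0.64. Of 11 histone genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.00233, and adjusted p = 0.375 with an estimated correlation), with HTA2 at 0.87 and HHF1 at 0.76. Histone genes have near-identical copies, so single values are uncertain.

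Of 21 chaperone genes driven by Hsf1, 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.32 (adjusted p = 7.53e-06, and adjusted p = 0.408 with an estimated correlation). SSA4, a heat-induced Hsp70, fell 2.84-fold and BTN2 fell 2.54-fold. Of 16 phosphate starvation genes 9 fell and 2 rose (9 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.00469, and adjusted p = 0.359 with an estimated correlation). SPL2, which acts on phosphate uptake, fell 4.09-fold, from 519 ± 0.317 to 127 ± 13.7, while GIT1 rose at 0.69. Ribosomal protein genes had 34 falls and 3 rises among 138 members (26 and 1 adjusted over the list alone), with a median of -0.08 (adjusted p = 0.00077, and adjusted p = 0.396 with an estimated correlation). The test did not call the lists of environmental stress (median -0.05, adjusted p = 0.146), ribosome biogenesis (-0.04, adjusted p = 0.201), strain markers (0.16, adjusted p = 0.0909), glucose-repressed genes (-0.01, adjusted p = 0.62), iron uptake (-0.06, adjusted p = 0.62), mating genes (-0.10, adjusted p = 0.964), glycolysis (mean 0.01 with a test direction below 0, adjusted p = 0.964) or tagged and pathway proteins (-0.04 with a mean of 0.20, adjusted p = 0.964). In the stress list 16 genes fell and 9 rose among 43 (18 and 9 adjusted over the list alone), among them SSA4, HSP42 at -0.96 and GAC1 at 1.05. Over all 6360 features 1187 fell and 1341 rose.

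The 10 largest rises were mostly features without an entry in the annotation: YOR041C at 4.23, YGR291C at 3.65, YBR124W at 3.50, YNL174W at 3.35, YCRX03C at 3.28, YAR069C at 3.27 and YLR232W at 3.27. Those with an entry were YDR042C, YHR214C-D at 3.75 and YBR298C-A, whose 127 reads in the Nab3 libraries stood against 1 read in the cassette libraries, a ratio of 122 with a 95% exact interval from 21.6 to 4874. YHR214C-D and YAR069C lie in repeated subtelomeric sequence and their reads are uncertain. The largest falls, besides PHO84 and SPL2, were AAD16 at -2.62, the NADPH dehydrogenase gene OYE3 at -2.55, LIN1 at -1.96, YML054C-A at -1.95, YOR012W at -1.64, the Rab GTPase-activating protein gene GYP5 at -1.60, the vacuolar aminopeptidase gene APE1 at -1.58 and RRT6 at -1.57. The count of changed features fell from 2528 to 1672 when cassette library 1 was left out. The falls numbered 721 without the trend in eBayes, 772 with DESeq2 and 649 without cassette library 1.

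**Figure D2:**
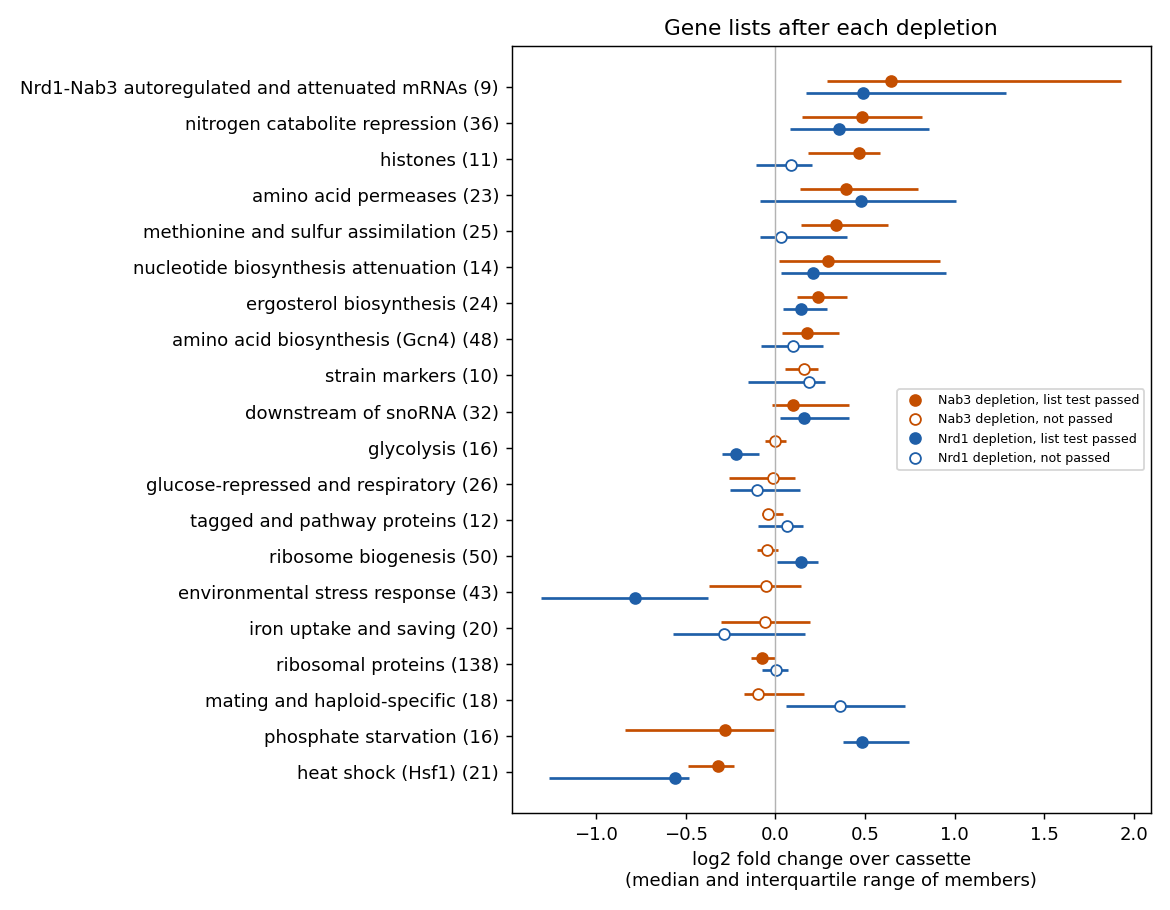
Median log2 fold change (points) and interquartile range (lines) over the tested members of each gene list after Nab3 or Nrd1 depletion, with the number of members tested in the Nab3 comparison in brackets; filled points passed the list test with the preset correlation. Phosphate starvation genes have a median of -0.28 after Nab3 depletion and 0.48 after Nrd1 depletion, and environmental stress genes -0.05 and -0.79.

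The comparison of Nrd1 depletion with the same cassette libraries asked the same of Nrd1. Signal rose on 23 of 36 nitrogen genes, 14 of 23 permeases, 5 of 9 early-terminated mRNA genes and 14 of 16 phosphate-starvation genes, and fell on 31 of 43 stress and 17 of 21 chaperone genes. The list calls were lost with an estimated correlation (adjusted p = 0.328 to 0.505 for these lists with an estimated correlation). NRD1 rose 4.20-fold, from 1720.0 ± 86.8 to 7222 ± 332 normalised reads (2.07 ± 0.07 SE, adjusted p = 1.73e-05). PHO84 rose 3.54-fold, from 2728 ± 352 to 9657 ± 1250.8 (1.82 ± 0.12 SE, adjusted p = 0.000158). HSP42, a small heat shock protein (chromosome IV, 806621 to 807748), fell 4.57-fold, from 641 ± 14.3 to 141 ± 29.6 (-2.19 ± 0.16 SE, adjusted p = 0.00021). Of 6347 features tested, 1110 rose and 1128 fell, of which 251 rose and 93 fell at least 2-fold.

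Nitrogen catabolite repression genes had 23 rises and 4 falls among 36 members (23 and 4 adjusted over the list alone, median 0.35, adjusted p = 0.000112, and adjusted p = 0.328 with an estimated correlation). DAL1, which encodes allantoinase, rose 4.69-fold and DAL80 rose 4.28-fold, while UGA1 fell at -0.61. Of 23 permeases 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.000408, and adjusted p = 0.328 with an estimated correlation), with UGA4 at 1.83 and AGP3 at 1.77. Of the 9 early-terminated mRNA genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.49, adjusted p = 0.00345, and adjusted p = 0.328 with an estimated correlation). IMD2 rose at 2.05, and TIS11 fell at -1.60, a call lost without the trend in eBayes. The nucleotide list had 6 rises and 1 fall among 14 members (8 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.00345, and adjusted p = 0.328 with an estimated correlation), with URA8 at 1.29. Of 32 genes downstream of a snoRNA 15 rose and 0 fell (15 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.000872, and adjusted p = 0.33 with an estimated correlation). YDR042C rose 21.6-fold, and TRS31, a subunit of the TRAPP complex (chromosome IV, 1403322 to 1404173, plus strand), rose 3.25-fold.

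Phosphate starvation genes had 14 rises and 1 fall among 16 members (14 and 1 adjusted over the list alone, median 0.48, adjusted p = 3.57e-05, and adjusted p = 0.328 with an estimated correlation), led by PHO84 and SPL2, which rose 2.20-fold. The 50 ribosome biogenesis genes had 15 rises and 0 falls (15 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.000521, and adjusted p = 0.328 with an estimated correlation). Ergosterol genes had 9 rises and 1 fall among 24 (9 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.0144, and adjusted p = 0.328 with an estimated correlation), with HMG1 at 0.70. Of 43 environmental stress genes 31 fell and 1 rose (33 and 1 adjusted over the list alone, median -0.79, adjusted p = 1.16e-10, and adjusted p = 0.328 with an estimated correlation). TMA10 fell 6.35-fold in it, from 683 ± 1.86 to 110 ± 35.8. Of 21 Hsf1-driven chaperone genes 17 fell and 0 rose (19 and 0 adjusted over the list alone, median -0.56, adjusted p = 1.49e-06, and adjusted p = 0.505 with an estimated correlation), with SSA4 at -1.86. The chaperone and stress lists share HSP42, HSP78, HSP104 and SSA4.

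Glycolytic genes had a median of -0.22 with 1 fall, TDH1 at -0.84, among 16 members (1 adjusted over the list alone, adjusted p = 0.0481, and adjusted p = 0.747 with an estimated correlation). That list call was lost at a mean of at least 50 (adjusted p = 0.0596), without cassette library 2 (median -0.15) and without Nrd1 library 1 (median -0.048). The test did not call the Gcn4 list (median 0.10, adjusted p = 0.0819), mating genes (0.36, adjusted p = 0.0819), iron uptake (-0.29, adjusted p = 0.208), glucose-repressed genes (-0.10, adjusted p = 0.265), sulfur genes (0.03, adjusted p = 0.273), tagged and pathway proteins (0.07, adjusted p = 0.39), strain markers (0.19, adjusted p = 0.473), ribosomal proteins (median 0.0008 with a test direction below 0, adjusted p = 0.691) or histones (adjusted p = 0.909, with a median of 0.09 and a test direction below 0). In the glucose-repressed list 2 genes rose and 6 fell among 26 (2 and 6 adjusted over the list alone), among them ICL1 at 0.65 and the hexose transporter gene HXT7, which has a near-identical copy in HXT6, at -1.42. In the iron list 2 rose and 9 fell among 20 (3 and 11 adjusted over the list alone), among them ARN2 at 0.84 and FET3, a multicopper oxidase of iron uptake, at -1.73.

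The largest rises were YHR214C-D at 4.68, YOR041C at 4.66, YDR042C at 4.43, YAR069C at 4.34, YGR291C at 3.45, YJL026C-A at 3.38, YBR124W at 3.16, YNL150W at 3.15 and YCRX03C at 3.07, beside YBR298C-A with 91 reads against 1 in the cassette libraries, a ratio of 127 with a 95% exact interval from 22.3 to 5088. The largest falls were OYE3 at -3.30, AAD16 at -2.99, TMA10, YNL194C at -2.36, the inositol phosphate synthase gene INO1 at -2.24, HSP42, SPG4 at -2.08, the hexokinase gene HXK1 at -2.07, HSP26 at -2.01 and YML131W at -1.98. The SPG4 call was lost without cassette library 1 (adjusted p = 0.0804, the highest of the settings tried). The count of changed features, 2238, was 640 without cassette library 1, 719 without cassette library 2 and 3617 without Nrd1 library 2, and the falls numbered 703 without the trend in eBayes. The Nrd1 libraries differed from each other with an SD of the log2 difference of 0.277, against 0.168 for the cassette libraries.

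The difference between the depletions was tested on the joint scale. Of 16 phosphate genes 12 lay lower, and of 43 stress genes 35 lay higher, after Nab3 than after Nrd1 depletion (adjusted p = 0.495 and adjusted p = 0.645 for the lists with an estimated correlation). PHO84 had 493 ± 4.69 normalised reads after Nab3 depletion against 11405 ± 1477 after Nrd1 depletion (difference -4.52 ± 0.10 SE, adjusted p = 5.53e-08), and SPL2 had 127 ± 13.7 against 1142 ± 23.5 (-3.17, adjusted p = 8.34e-07). PHM6, a phosphate-responsive gene, differed by -2.23 and YHR022C-A by -2.02. INO1 had 5568 ± 1763 against 655 ± 42.5 (3.05 ± 0.26 SE, adjusted p = 0.000201), and YEL073C, SAM2, YDR034W-B and TMA10 were higher after Nab3 depletion by 2.54, 2.30, 1.84 and 1.73. YDR194W-A, with 1 to 19 reads per depleted library, differed by -2.32, or by -1.52 without Nab3 library 3. Its call was lost then, without cassette library 1 or 2, and without the trend in eBayes (adjusted p = 0.0679). Its difference stayed at -2.32 without either cassette library, since these enter differences between depletions only through the spread.

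Among 43 environmental stress genes 35 were higher and 0 lower after Nab3 depletion (36 and 0 adjusted over the list alone, median 0.71, adjusted p = 2.22e-14, and adjusted p = 0.645 with an estimated correlation). Of 16 phosphate genes 12 were lower and 1 higher (13 and 1 adjusted over the list alone, median -0.75, adjusted p = 2.18e-09, and adjusted p = 0.495 with an estimated correlation). Of 50 ribosome biogenesis genes 16 were lower and 0 higher (24 and 0 adjusted over the list alone, median -0.16, adjusted p = 1.25e-08, and adjusted p = 0.645 with an estimated correlation). The list test also called chaperone genes, with 7 of 21 higher and 0 lower (12 and 0 adjusted over the list alone, median 0.31, adjusted p = 0.00199), and sulfur genes, with 8 of 25 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.00738). It called glycolytic genes with 3 of 16 higher and 0 lower (3 and 0 adjusted over the list alone, median 0.21, adjusted p = 0.0321). It called ribosomal protein genes with 6 of 138 lower and 3 higher (0 and 0 adjusted over the list alone, median -0.063, adjusted p = 0.0276). With an estimated correlation the adjusted p was 0.645 for chaperone, sulfur and glycolytic genes and 0.766 for ribosomal protein genes. Nitrogen catabolite repression genes (0.12, adjusted p = 0.0898), permeases (0.01, adjusted p = 0.861), genes downstream of a snoRNA (-0.05, adjusted p = 0.163) and early-terminated mRNA genes (0.16, adjusted p = 0.141) were not called.

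In all, 1340 of 6385 features differed, 771 of them higher and 569 lower after Nab3 depletion. Scaling changed that balance: upper-quartile scaling gave 634 higher and 817 lower, and scaling to the protein-coding total gave 619 and 747. The count was 775 without the trend in eBayes, 792 and 798 without cassette library 1 or 2, 478 and 409 without Nab3 library 2 or 3, and 2080 without Nrd1 library 2.

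Both depletions moved many features the same way. Of 6330 features tested in both, 738 rose in both, 576 fell in both and 64 were called in opposite directions. Independent lists of these sizes would share 232 rises and 211 falls. Unchanged groups were simulated 50 times, each time with a simulated control that both comparisons shared in place of the real cassette libraries. They had on average 0.88 and 1.12 rises called in all, too few to say how many shared calls the common controls give. Log2 fold changes correlated across features, which are not independent replicates, with r = 0.776, against 0.490 in the simulations, and their covariance was 0.177 against 0.0101, a difference of 0.167. The cassette group has 2 libraries and cannot be split into groups of 2, so part of the excess may come from the shared controls. The simulations hold only noise between libraries. They leave out the strain and the lack of rapamycin that set the cassette apart from both depleted groups. The difference of 0.167 therefore does not measure a shared effect of the depletions. NRD1, IMD2, DAL80, UGA4 and YDR042C rose in both, and OYE3, AAD16, SSA4 and HSP42 fell in both.

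**Figure D3:**
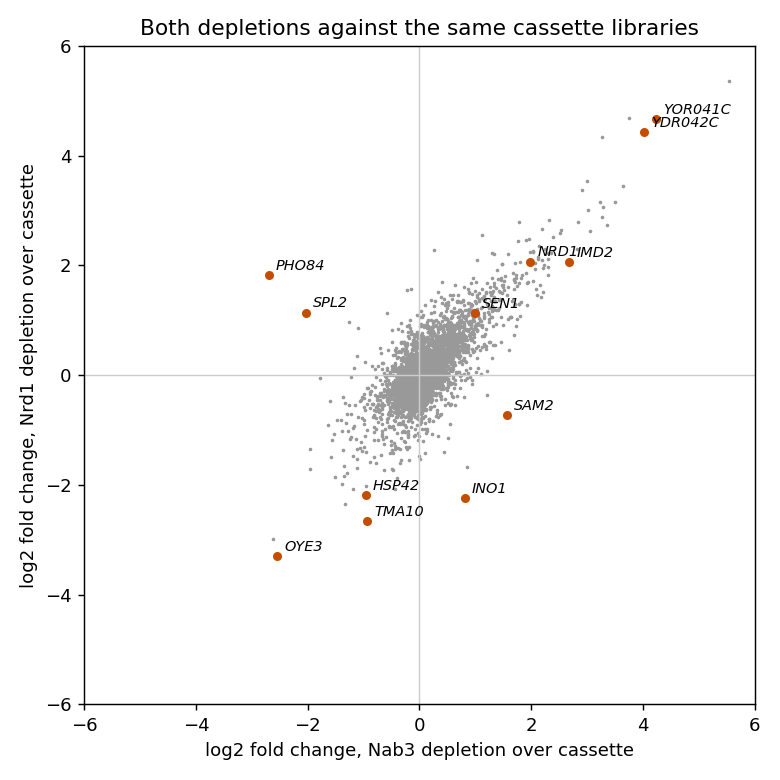
Log2 fold change over the cassette after Nab3 depletion (horizontal) and after Nrd1 depletion (vertical), 1 grey point per feature tested in both, with 12 genes marked in colour. PHO84 and SPL2 lie at -2.70 and -2.03 on the Nab3 axis and at 1.82 and 1.14 on the Nrd1 axis, and both axes share the cassette libraries.

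The authors' deposited table for Nab3 called 1025 features higher and 769 lower at their adjusted p under 0.05, and 1790 of these 1794 were called here in the same direction. The authors' deposited table for Nrd1 called 760 higher and 788 lower, and 1533 of the 1548 were shared. Replicates correlated across features with r between 0.991 and 0.997, and libraries of different groups with r between 0.963 and 0.977, where features are not independent replicates. The SD of the log2 difference between the libraries of a group was 0.174 for the cassette and 0.178 for Nab3 in the Nab3 table.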

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

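The tests in this part that weigh an explanation were chosen after the results were seen.

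Each result here was called by the test of the difference between the depletions, for lists with the preset correlation. With an estimated correlation the list differences were not called (adjusted p = 0.495 for phosphate genes, 0.766 for ribosomal protein genes and 0.645 for the other lists here). Phosphate starvation genes had a median Nab3 minus Nrd1 log2 difference of -0.75, with PHO84 at -4.52, SPL2 at -3.17 and PHM6 at -2.23. INO1 differed by 3.05 and YEL073C by 2.54. The differences were 2.30 for SAM2, 1.84 for YDR034W-B, 1.73 for TMA10, -2.02 for YHR022C-A and -2.32 for YDR194W-A. The YDR194W-A call was lost in several settings, and its difference was -1.52 without Nab3 library 3. The median differed by 0.22 for methionine and sulfur genes, 0.21 for glycolytic genes, -0.063 for ribosomal protein genes and -0.16 for ribosome biogenesis genes. Of 147 genes named by the fixed rule, 60 had a called difference, which includes the 10 that the rule picks for the largest differences. The 64 features called in opposite directions were selected for differing, so their called differences are no separate evidence.

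After Nrd1 depletion 31 of 43 environmental stress genes fell, and 18 and 17 of 21 Hsf1-driven chaperone genes fell after Nab3 and Nrd1 depletion (adjusted p = 0.328, 0.408 and 0.505 for the lists with an estimated correlation). After Nab3 depletion 16 of the 43 stress genes fell and 9 rose. A stressed state of the shared cassette libraries would lower both depletions alike. For the stress list the median Nab3 minus Nrd1 difference was 0.71 and lay between 0.56 and 0.85 in the 4 pairs of libraries. The list was flagged for this same difference and the pairs reuse the same libraries, so this is no separate test. The cassette libraries alone would not give such a difference, though a part of the fall may still come from them. For the chaperone list the median difference was 0.31 but lay between 0.062 and 0.54 in the pairs, so the cassette libraries stay open there. Bootstrap intervals over genes, 0.54 to 0.81 for the stress list and 0.21 to 0.38 for the chaperone list, treat correlated genes as independent. Strain and depleted protein differ together between the Nab3 and Nrd1 libraries, and the rapamycin time of the Nab3 libraries is not given in the sources used here, so a biological effect of losing Nrd1 stays open and untested.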

How the results depend on the processing

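The restriction to features with a reference entry was chosen after seeing the data. It left each count of changed features within 1.5 times its value, as did the settings not given here. Without the trend in eBayes, falls numbered 721 for Nab3 and 703 for Nrd1, and between depletions 775 features differed (435 higher, 340 lower). DESeq2 gave 772 falls for Nab3. Fits that leave out a library have fewer libraries, and the lone library of a group is assumed to vary like the other groups. Leaving out each library in turn gave 1672 to 2803 changed features for Nab3 (falls 649 to 1401), 640 to 3617 for Nrd1 (rises 375 to 1751, falls 265 to 1866), and 409 to 2080 between depletions (higher 275 to 1158, lower 134 to 922). Without either Nrd1 library only the cassette pair sets the spread, and it differs less (SD of the log2 difference 0.168 against 0.277 for Nrd1). Whether this explains the high counts without Nrd1 library 2 was not tested. edgeR called 2539, 2281 and 1343 features. At an adjusted p under 0.01, the shared rises numbered 412, the shared falls 240 and the authors' Nrd1 calls 1027, since the threshold is stricter.

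With an estimated correlation 0 of 12 lists after Nab3 depletion and 0 of 11 after Nrd1 depletion passed, the lowest adjusted p being 0.226 and 0.328. This setting tests on 2 residual degrees of freedom per depletion, so it cannot tell correlated genes from low power. For amino acid permeases after Nab3 depletion the camera p went from 8.8e-07 to 0.032. Their estimated correlation, -0.0048, lay below the preset 0.01, as did that of nitrogen catabolite repression genes after Nab3 depletion (0.0062). Other lists lay far above it. Chaperone genes had 0.56 after Nab3 and 0.61 after Nrd1 depletion, and stress genes 0.24 after Nrd1 depletion. The preset p-values of such lists may be too small. The nitrogen catabolite repression medians stayed at 0.48 and 0.35 because estimating the correlation changes only the test. Leaving out a library gave 11 to 16 lists for Nrd1. Medians of histone genes ranged from 0.47 without Nrd1 library 2, where the list was called higher, down to -0.25 without Nrd1 library 1, and those of ribosomal protein genes from -0.11 to 0.11, where without Nrd1 library 2 the list was called higher. The cause was not tested. List tests were run at a mean of at least 50, with both scalings, with the replicate block for Nrd1 and without each library, and 12 of 12 list calls for Nab3 and 10 of 11 for Nrd1 were kept in these. They were not run with other pseudocounts, without the filter, without the trend in eBayes, with edgeR or with DESeq2.

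The replicate block gave 2243 calls for Nrd1 (edgeR with the block, 2309). Same-numbered libraries did not deviate together (r = 0.0133 across features, 2 pairs). No paired analysis was possible for Nab3 or for the difference, because the Nab3 columns are numbered 2 and 3.

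Of the called named genes, 63 of 78 for Nab3, 46 of 65 for Nrd1 and 9 of 10 for the difference kept their call in every setting, and 0 reversed. At 7395659 reads in the shallowest library, features near a mean of 10 limit what can be called.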

Other observations

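Tests on nitrogen genes, the lists from the authors' marks and the tests by the cassette mean were chosen after the results were seen. The other tests on features without a reference entry were written before their results.

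Of 32 genes marked Proteasome by the authors 29 fell and 0 rose after Nab3 depletion (median -0.31, camera adjusted p = 6.93e-10, and adjusted p = 0.158 with an estimated correlation), and 29 fell and 0 rose after Nrd1 depletion (median -0.35, adjusted p = 8.7e-09, and adjusted p = 0.412 with an estimated correlation). PRE4, a catalytic-core subunit, fell at -0.52 and -0.31, and SEM1, a subunit of the lid, at -0.36 and -0.68. Both comparisons share the cassette libraries, so these falls are not independent of each other, and the difference between depletions was not called (median 0.08, adjusted p = 0.161). These genes were picked after their values were seen, and how the authors chose their marks is not given in the sources used here, so the marks are not independent evidence. Their Heatshock mark had 6 falls among 7 genes in each depletion, with medians of -0.49 and -1.37. Their Fold mark had 11 and 9 falls among 15 genes, and their Degrad mark 2 and 5 falls among 10. Their NCR mark had 46 rises and 10 falls among 80 tested genes for Nab3 and 35 and 17 for Nrd1, and their Nitrogen mark 23 and 5 among 71 for Nab3 and 16 and 10 for Nrd1. Their Ribi mark had 20 rises and 24 falls among 171 genes for Nab3 and 58 and 4 for Nrd1. Their Ribosome mark had 2 rises and 31 falls among 129 genes for Nab3 and 2 and 4 for Nrd1, and their Glycolytic mark 1 rise and 0 falls among 14 for Nab3 and 0 and 2 for Nrd1.

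INO1, ITR1, CHO1 and PSD1 were picked from the 64 features called in opposite directions after their values were seen, and no enrichment was tested. Their log2 fold changes were 0.81, 0.51, 0.31 and 0.32 after Nab3 depletion and -2.24, -1.14, -0.70 and -0.76 after Nrd1 depletion. INO1 had 1942 and 3538 normalised reads in cassette libraries 1 and 2 on the scale of the Nrd1 comparison, so the size of its changes depends on the cassette library.

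Of 36 nitrogen catabolite repression genes 27 rose and 1 fell after Nab3 depletion, and 23 rose and 4 fell after Nrd1 depletion (adjusted p = 0.226 and adjusted p = 0.328 for the list with an estimated correlation). In cells sensitive to it, rapamycin inhibits TORC1, which would raise these genes and lower ribosome biogenesis genes. Whether these strains are sensitive to rapamycin was not tested. After Nrd1 depletion the ribosome biogenesis median was 0.14 (95% bootstrap interval 0.09 to 0.20, 50 genes, 0.142 to 0.150 over the 4 pairs of libraries), which argues against general TORC1 inhibition there unless the cassette libraries lie low on these genes, though the list call was lost with an estimated correlation (adjusted p = 0.328 with an estimated correlation) and the bootstrap treats genes as independent. After Nab3 depletion it was -0.044 (-0.069 to -0.0091, list not called). Ribosomal protein genes had 34 falls among 138 there (median -0.08, camera adjusted p = 0.00077, and adjusted p = 0.396 with an estimated correlation). Over all 6360 features 1187 fell. These shifts are small and do not decide, so TORC1 inhibition stays open after Nab3 depletion. The shared cassette libraries may also lie low on nitrogen genes, and the median difference between depletions, 0.12 (0.03 to 0.18), does not decide this, since both carry the same control.

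Features without a reference entry rose more often than the rest: 204 of 576 after Nab3 depletion against 1137 of 5784, and 194 of 568 after Nrd1 depletion against 916 of 5779. At a mean of at least 200 the shares called higher had ratios of 1.54 (1.17 to 1.93) and 2.63 (2.10 to 3.20), and medians of 0.29 and 0.51 lay above those of lists matched on mean and length, but these means include the depleted libraries, so a rise can carry a feature past them and neither test decides. At a cassette mean of at least 200 the share was 21.7% against 18.6% after Nab3 depletion, a ratio of 1.17 (95% bootstrap interval 0.812 to 1.55, Fisher exact p = 0.384), so counts near the floor remain a possible explanation, and 30.5% against 14.6% after Nrd1 depletion, a ratio of 2.09 (1.53 to 2.67, Fisher exact p = 5e-06), which argues against them. Lists matched on length and cassette mean reached 0.14 and 0.31 against feature medians of 0.24 and 0.44. After Nrd1 depletion this argues against low expression and short length as the whole cause. After Nab3 depletion it points the other way from the shares at a cassette mean of at least 200, so low expression stays open there. Neighbours of the 185 and 172 features called higher (chosen for having risen, medians 1.01 and 1.15) had medians of 0.0344 (-0.016 to 0.065) and 0.00784 (-0.028 to 0.044) times those. Transcription that runs past a neighbour's end or starts antisense after depletion may add reads there and was not tested, since the strand setting of the counts is not given.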
